A study of Homo sapiens with 6 samples.

How the data were processed

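PolyA RNA of AALE cells with a control vector (3 libraries) or an NRG1 vector (3 libraries) was prepared with a TruSeq kit, per the labels' protocols. Groups and replicate numbers came from the sample titles. The deposited expected counts, not whole numbers and not normalized, covered 57736 genes by Ensembl identifier. The submitters' processing notes name STAR 2.5.3a, RSEM 1.3.0, FastQC 0.11.3, MultiQC 0.9 and the hg19 build without their roles; the annotation is not given in the sources used here. RSEM is a tool that shares reads fitting several genes among them, so counts of genes with close copies are uncertain. A further deposited table, named for CPM, held log2 values of 14759 genes that went below 0. These deposited log2 values equalled, to within 1e-09, log2 CPM with TMM scaling and a prior count of 0.25 computed from the deposited expected counts of the same genes; without scaling the largest difference was 0.0836. The design had assumed CPM in that table, so the values were turned back to CPM as powers of 2 before the pseudocount alternatives. No deposited column of another sample was left over.

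Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood test of NRG1 against control, no covariate). Of 57736 genes, 29981 had a count above 0 and 15421 were tested, which held at least 99.7% of the expected counts of every library. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and 2-fold means a fitted log2 fold change of at least 1. Levels are TMM-scaled CPM of the rounded counts; principal components used log2 CPM with a prior count of 2. Total expected counts ran from 8612234 to 13207620 per library. A gene at 10 CPM therefore rested on about 100 counts, and at lower levels counting error adds to the spread between libraries.

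Gene symbols came from a name table matched on identifiers, for 51959 of 57736 genes. GC content and exon number came from GENCODE 29, a GRCh38 annotation, matched on identifiers, with a GC value for 97.4% of the tested genes; none of its coordinates are given.

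There were 35 gene lists (780 entries, 754 of them in the count table), written before the data were examined, as were the design and a first set of alternative settings. The 32 lists with at least 5 tested genes were tested with camera (limma 3.58.1) at its preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. The lists for endothelial cells (1 gene tested), leukocytes (4 tested) and mitochondrially encoded genes (0 tested) were not tested. The rule for named genes took NRG1 in every library, the 10 largest increases and 10 largest decreases among genes with a symbol, an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and groups that did not overlap, and up to 4 members of each list described with the smallest adjusted p. Only NRG1 met the middle part of the rule. Some genes that met the last part are not reported here. Other genes are named as chosen after their values were seen.

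Settings chosen before the data were examined were DESeq2 1.42.0 with its own size factors, upper-quartile scaling, library totals alone, no low-count filter, a filter of at least 1 CPM in 3 libraries, limma-trend on log2(CPM + 1) and log2(CPM + 0.25), limma-voom without rounding, the replicate number as a block, leaving out each library in turn, camera with an estimated correlation, and fry. DESeq2 left 15 adjusted p-values undefined, which count as not called. Chosen after seeing the data were a comparison of 2 against 2 libraries without control 3 and NRG1 1, limma-voom with a quality weight per library, edgeR's older dispersion method, a GC correction per library with all 6 and with 4 libraries, and the ERBB ligand list without NRG1. Removing libraries for their distance from the rest lowers the spread within groups, so p-values of the 2 against 2 comparison are too small by an unknown amount.

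The tests were tried on simulated counts of 15421 genes with the means, library sizes and dispersions of the real libraries. In the 3 against 3 comparison edgeR recovered 20 of 100 genes changed 2-fold and 78 of 100 changed 4-fold, with 11 false calls among 109. DESeq2 recovered 41 and 87 of 100, with 39 false calls among 167. In the 2 against 2 comparison edgeR recovered 68 and 90 of 100, with 18 false calls among 176. The simulated genes varied independently of each other, and no library was removed for its distance. These rates therefore do not cover shifts shared by many genes of a library, or the choice of the 4 libraries.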

Results

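The data came from AALE cells, a line of human bronchial basal epithelial cells immortalised with SV40 genes and telomerase. Stable pools of cells carried either a control lentiviral vector or a vector that overexpresses NRG1, the gene of the growth factor neuregulin, a ligand of the ERBB family of receptors. PolyA RNA was sequenced from 3 control libraries and 3 NRG1 libraries. The series asks how NRG1 changes gene expression in airway epithelial cells. The deposited table held expected counts for 57736 genes. The total expected count was 12353550, 9549284 and 13207620 in control 1 to 3, and 8612234, 10609067 and 9062257 in NRG1 1 to 3. The labels do not say that the libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

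NRG1 (ENSG00000157168, a protein-coding gene on chromosome 8) was the targeted gene, and its level separated the groups in every library. Its TMM-scaled CPM was 11.6, 7.87 and 12.3 in the 3 control libraries and 6647, 3854 and 3781 in the 3 NRG1 libraries. The group means were 10.6 ± 2.37 and 4761 ± 1634 CPM (SD, n = 3 each). NRG1 rose by a log2 fold change of 8.80 (SE 0.38), with an adjusted p of 0.00012 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In the NRG1 libraries this gene took 0.466% of all expected counts on average. A two-sided exact permutation test of the log2 level gave p = 0.1, the smallest that 3 against 3 libraries allow. Reads from the vector and from the cell's own gene could not be told apart.

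Beyond NRG1, the NRG1 libraries held less RNA of FN1, COL5A1, OASL, KRT17 and KRT14, and more of MUC1, KRT19, LCN2 and FTH1, than the control libraries. None of these genes passed the main test that NRG1 passed, though some passed in other settings, as described further on. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1 of 15421 genes passed the threshold, NRG1 itself, which was also changed at least 2-fold; 1 gene was higher and 0 were lower. At an unadjusted p under 0.05 there were 1819 genes, 783 higher and 1036 lower, against 771 expected if no gene differed. A split of the same libraries that set control 1, control 3 and NRG1 1 against the rest gave 2042. The excess over 771 therefore does not show by itself an effect of NRG1. In 1443 genes the 3 NRG1 libraries all lay above the 3 controls, and in 1575 genes all lay below, together 19.6% of the genes. Without ties, each gene separates in 1 of the 10 splits into 3 and 3, so 10% is the average over the splits. The share in the other splits was not computed, so 19.6% does not show by itself an effect of NRG1. DESeq2 on the same counts called 209 genes, 92 higher and 117 lower, of which 168 were changed at least 2-fold. Control 3 and NRG1 1 stood apart from their groups, as described further on. Without NRG1 1 alone, edgeR called 37 genes, 27 higher and 10 lower. Without both of these libraries, a comparison chosen after seeing the data, edgeR called 1515 genes, 777 higher and 738 lower. Among these 1515 genes, the left-out NRG1 1 lay on the control side of the mean of control 1 and control 2 in 664, and the left-out control 3 lay on the NRG1 side of it in 636.

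**Figure D1:**
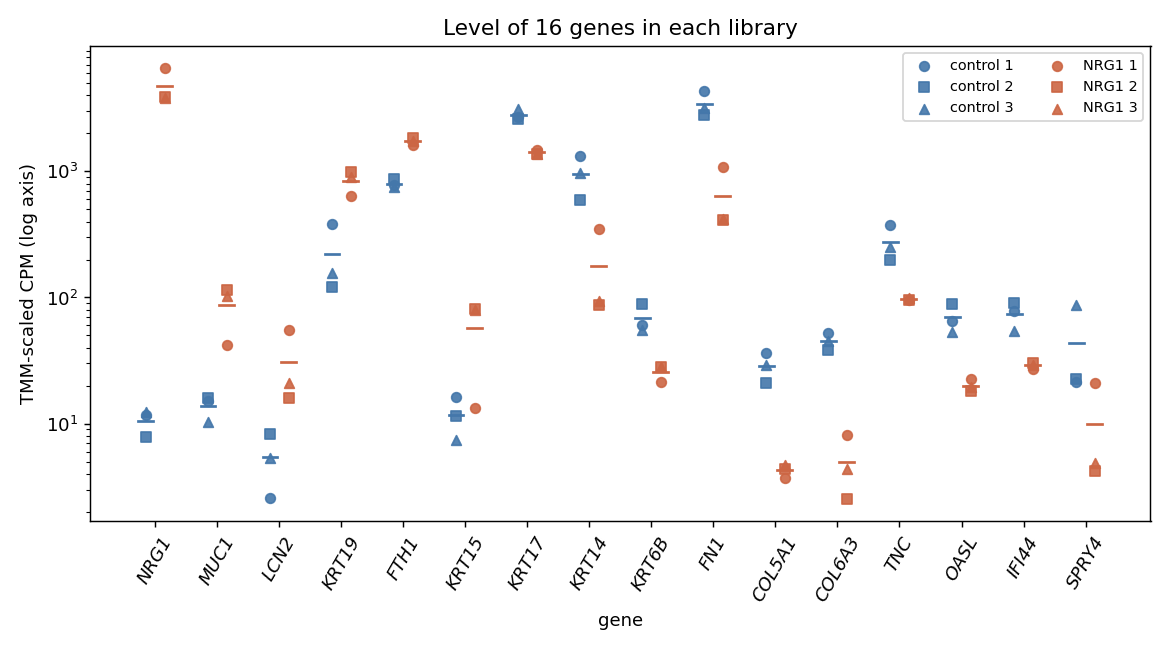
TMM-scaled CPM (log axis) of 16 genes in each of the 6 libraries; blue symbols are control libraries, orange symbols are NRG1 libraries, the symbol shape gives the replicate number and the short lines are the group means of 3 libraries. NRG1 lies at 7.87 to 12.3 CPM in the controls and at 3781 to 6647 CPM in the NRG1 libraries, and KRT15 is the gene shown whose groups overlap.

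The mesenchymal transition list holds matrix, cytoskeletal and transcription factor genes typical of mesenchymal cells, and its median was lower in each NRG1 library than in each control. FN1, the matrix protein fibronectin, was at 3420 ± 782 CPM in control and 638 ± 385 CPM in NRG1 (SD, n = 3 each). COL5A1, a fibrillar collagen chain, was at 28.9 ± 7.77 CPM in control and 4.26 ± 0.494 CPM in NRG1, a log2 fold change of -2.76 (SE 0.30). TAGLN, an actin-binding protein of contractile cells, had a log2 fold change of -2.09 (SE 0.29), and TNC, the matrix glycoprotein tenascin-C, one of -1.51 (SE 0.23). Of the 24 members tested, 13 were lower in all 3 NRG1 libraries than in all 3 controls and 1 was higher. The list fell by camera with the preset correlation (median log2 fold change -1.05, adjusted p = 4.62e-17); the adjusted p was 0.15 with an estimated correlation. None of its members passed edgeR over all genes (0 of 24; adjusted p 0.0634 for COL5A1, 0.113 for TAGLN, 0.15 for TNC and 0.17 for FN1), 13 members were lower when adjusted over the list alone, 14 were lower and 1 higher at an unadjusted p under 0.05, and DESeq2 called 8, all lower.

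The fibroblast and TGF-beta target lists went the same way. For TGF-beta targets the median relative to the control mean was -0.33 in NRG1 1, about level with -0.29 in control 2. COL6A3, a collagen chain of the pericellular matrix, was at 45.3 ± 7.02 CPM in control and 5.01 ± 2.88 CPM in NRG1, a log2 fold change of -3.21 (SE 0.38), and DCN, the proteoglycan decorin, had one of -1.58 (SE 0.36). Both belong to the fibroblast list, of which 3 of 6 members tested were lower in all NRG1 libraries. Among TGF-beta targets, COL4A1 of the basement membrane had a log2 fold change of -1.20 (SE 0.22), and TGFBI, a secreted adhesion protein, had one of -1.01 (SE 0.26). In this list 9 of 22 members were lower in all NRG1 libraries and 0 were higher; TNC is a member of both this and the mesenchymal list. By camera with the preset correlation both lists fell, with an adjusted p of 2.05e-05 for fibroblast genes (0.15 is the adjusted p with an estimated correlation) and of 5.31e-08 for TGF-beta targets (0.326 is the adjusted p with an estimated correlation). In edgeR 0 members of either list passed over all genes; adjusted over the list alone, 2 and 5 were lower, at an unadjusted p under 0.05 it was 3 and 9, and DESeq2 called 2 and 4. Fibroblast markers outside the tested genes summed to 56, 34 and 46.5 expected counts in control 1 to 3 and 16, 16 and 28 in NRG1 1 to 3. These sums are not scaled to the library totals, which differ. In NRG1 3, PDGFRA held 17 of the 28 counts, against 12, 13 and 7.49 in control 1 to 3.

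In the type I interferon response list, OASL and IFI44 were at lower levels in all 3 NRG1 libraries than in the controls, while the list's median in NRG1 2 and NRG1 3 lay about level with control 3. OASL, an antiviral protein induced by interferon, was at 69.4 ± 18.1 CPM in control and 20.05 ± 2.21 CPM in NRG1, a log2 fold change of -1.79 (SE 0.23). IFI44 had a log2 fold change of -1.36 (SE 0.22), RIGI, a sensor of viral RNA, one of -1.10 (SE 0.19), and HERC5, a ligase for the ubiquitin-like protein ISG15, one of -1.13 (SE 0.24). Of 32 members, 27 had a fold change below 0, and 11 were lower in all 3 NRG1 libraries than in all controls. The list fell by camera with the preset correlation (median log2 fold change -0.79, adjusted p = 4.49e-12), with an adjusted p = 0.349 with an estimated correlation. Over all genes edgeR called 0 members, 9 were lower when adjusted over the list alone, 12 were lower at an unadjusted p under 0.05, and DESeq2 called 5. The median of the list relative to the control mean was -1.14 in NRG1 1, against -0.41 and -0.45 in NRG1 2 and NRG1 3 and -0.40 in control 3.

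Markers of basal and squamous cells went both ways: 14 of 19 basal and 13 of 25 squamous genes had a fold change below 0. KRT17 was at 2811 ± 290 CPM in control and 1410 ± 63.2 CPM in NRG1, and KRT14, a keratin of basal cells, was at 959 ± 366 and 176 ± 148 CPM. The basal keratin KRT15 went the other way, with 13.4 CPM in NRG1 1, inside the control range of 7.49 to 16.2 CPM, and 80.4 and 79.4 CPM in NRG1 2 and NRG1 3. NGFR, a receptor of basal cells, was at 302 CPM in control 3, against 18.3 and 46.8 CPM in the other controls and 13.6 to 15.7 CPM in the NRG1 libraries. In the squamous list, KRT6B had a log2 fold change of -1.39 (SE 0.24), and KRT1, SPRR3 and SPRR2E, genes of the cornifying layers, had means of 2.65, 7.60 and 3.48 CPM in control and of 0.176, 1.41 and 0.284 CPM in NRG1. The airway basal cell list (19 members tested) and the squamous differentiation list (25 tested) both fell by camera with the preset correlation, with adjusted p-values of 0.00704 and 0.000269. The adjusted p-values were 0.349 and 0.565 with an estimated correlation. edgeR called 0 members of either list over all genes; adjusted over the list alone, 3 basal genes were lower and 1 higher, and 7 squamous genes were lower and 1 higher. At an unadjusted p under 0.05 there were 9 genes in each list, and DESeq2 called 2 basal genes as lower and 1 as higher, and 4 squamous genes as lower. The basal call was lost without control 1 (adjusted p = 0.135) and the squamous call without NRG1 1 (adjusted p = 0.339) and in the 2 against 2 comparison (adjusted p = 0.19); the squamous list's median was -1.83 in NRG1 1 and -0.23 and -0.08 in NRG1 2 and NRG1 3. Keratin and SPRR genes have close copies, so their counts are uncertain where reads fit more than 1 gene.

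As lists, epithelial and secretory genes were higher in NRG1 2 and NRG1 3, and KRT19 and MUC1 were higher in all 3 NRG1 libraries. KRT19, a keratin of simple epithelia, was at 219 ± 142 CPM in control and 841 ± 186 CPM in NRG1 (SD, n = 3 each), a log2 fold change of 1.94 (SE 0.42). MUC1, a transmembrane mucin, was at 13.8 ± 3.09 and 87.1 ± 39.2 CPM, a log2 fold change of 2.66 (SE 0.39), and LCN2, a secreted iron-scavenging protein, was at 5.39 ± 2.85 and 30.7 ± 21.2 CPM. The mucin MUC16 was at 0.371 CPM in NRG1 1, inside the control range of 0.081 to 1.16 CPM, and at 30.5 and 39.4 CPM in NRG1 2 and NRG1 3. CREB3L1 was lower, with a log2 fold change of -1.34 (SE 0.41). EHF and ELF3, transcription factors of epithelial cells, had log2 fold changes of 1.33 (SE 0.36) and 2.17 (SE 0.62), and EPCAM, an adhesion molecule, had one of 0.65 (SE 0.18). By camera with the preset correlation, the epithelial junction and identity list (32 tested, 27 above 0) and the secretory and mucous cell list (7 tested, 6 above 0) rose, with adjusted p-values of 7.1e-05 and 9.97e-05. The adjusted p-values were 0.326 and 0.15 with an estimated correlation. edgeR called 0 members of either list over all genes; adjusted over the list alone, 1 epithelial gene was higher, and 3 secretory genes were higher and 1 lower. At an unadjusted p under 0.05 there were 8 epithelial and 4 secretory genes, and DESeq2 called 3 and 2, all higher. The median of the secretory list was -0.30 in NRG1 1 and 1.69 and 1.45 in NRG1 2 and NRG1 3, and that of the epithelial list was 0.053 in NRG1 1, inside the control range, and 0.38 and 0.32 in the others. The 16 secretory genes outside the tested set summed to 19, 13 and 454 expected counts in control 1 to 3 and to 7, 21 and 626 in NRG1 1 to 3, so airway secretory transcripts were also present in control 3 and NRG1 3 at trace levels.

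**Figure D2:**
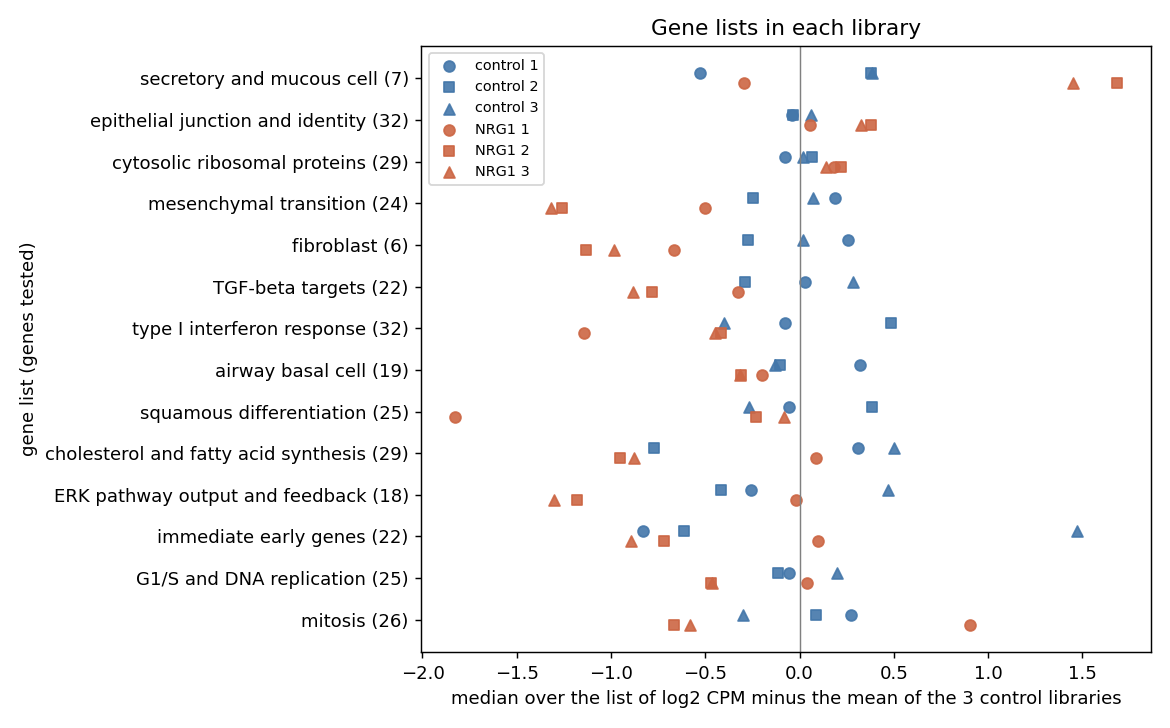
Median over each of 14 gene lists of a gene's log2 CPM minus its mean in the 3 control libraries, for each library; blue symbols are control libraries, orange symbols are NRG1 libraries, the symbol shape gives the replicate number, and the number of tested genes stands in brackets. The mesenchymal transition medians lie at -0.50, -1.26 and -1.32 in NRG1 1 to 3, below the 3 controls, whereas the mitosis medians lie at 0.90 in NRG1 1 and at -0.67 and -0.58 in NRG1 2 and NRG1 3.

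Among genes of the ERBB pathway itself, NRG1 was the member that passed edgeR. HBEGF, another ERBB ligand, was at 33.0, 40.2 and 198 CPM in control 1 to 3 and at 31.3, 14.9 and 17.3 CPM in NRG1 1 to 3, and DESeq2 called it as lower (adjusted p = 0.0459; 0.358 in edgeR). The ERBB ligand list was called as higher (8 tested, adjusted p = 0.000215 by camera with the preset correlation and 0.15 with an estimated correlation) although its median log2 fold change was -0.14 and its mean 0.88. The call was lost in limma-trend on log2(CPM + 1) (adjusted p = 0.277), in limma-voom without rounding (0.457) and with quality weights (0.984). Without NRG1 its 7 other members had a median of -0.22 and a camera p of 0.44. PTK6, a cytoplasmic tyrosine kinase, was at 23 ± 4.54 CPM in control and 46.2 ± 8.01 CPM in NRG1, and SHC1, an adaptor of receptor tyrosine kinases, was at 483 ± 13 and 340 ± 4.78 CPM (SD, n = 3 each). Neither passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes (adjusted p = 0.266 and 0.315). Of the 16 ERBB receptor and regulator genes tested, 0 passed edgeR over all genes, 2 had an unadjusted p under 0.05 and DESeq2 called PTK6 and SHC1; adjusted over the list alone 1 was higher and 1 lower. That list was not called (adjusted p = 0.498 by camera).

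The list of ERK output and feedback genes was not called as higher with NRG1. SPRY4, a feedback inhibitor of the pathway, was at 21.5, 22.6 and 87.0 CPM in control 1 to 3 and 20.9, 4.20 and 4.89 CPM in NRG1 1 to 3, and the phosphatase gene DUSP4 was at 72.8 ± 15.8 CPM in control and 42.7 ± 18 CPM in NRG1. Of 18 ERK output and feedback genes, 16 had a fold change below 0, and 1 was lower in all NRG1 libraries. The list fell by camera with the preset correlation (median -0.87, adjusted p = 7.1e-05), with an adjusted p = 0.565 with an estimated correlation. Its median relative to the control mean was -0.26, -0.42 and 0.47 in control 1 to 3. It was -0.02 in NRG1 1, inside the control range, and -1.18 and -1.30 in NRG1 2 and NRG1 3. Immediate early genes, which answer to growth factors within minutes, also fell by camera (22 tested, median -0.67, adjusted p = 0.0253), with an adjusted p = 0.749 with an estimated correlation. Their direction turned without control 3: the median was then 0.39 and the adjusted p 0.0609. The call was also lost without NRG1 2 (adjusted p = 0.104), without NRG1 3 (adjusted p = 0.16) and in the 2 against 2 comparison (adjusted p = 0.245). The level of the immediate early gene KLF4 was 141 ± 18.5 CPM in control and 105 ± 10.8 CPM in NRG1, and that of NR4A1 was 90.6 CPM in control 3 against 8.79 and 9.79 CPM in the other controls. In both lists edgeR called 0 genes over all genes tested and 0 when adjusted over the list alone, 2 ERK and 4 immediate early genes had an unadjusted p under 0.05, and DESeq2 called 0.

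The medians of the DNA replication and mitosis lists were lower in NRG1 2 and NRG1 3 than in each control, but not in NRG1 1. E2F1, a transcription factor of entry into S phase, was at 133 ± 31.3 CPM in control and 82.0 ± 3.69 CPM in NRG1, and CDC6, a licensing factor of replication, was at 180 ± 77.6 and 74.1 ± 41.6 CPM. The G1/S and DNA replication list fell by camera with the preset correlation (25 tested, median -0.17, adjusted p = 0.00179), with an adjusted p = 0.565 with an estimated correlation. Its median relative to the control mean was 0.04 in NRG1 1 and -0.47 in both other NRG1 libraries. The mitosis list was not called (26 tested, median 0.03, mean 0.05, camera direction down, adjusted p = 0.651; adjusted p = 0.914 with an estimated correlation). AURKB, a mitotic kinase, was at 60.8 ± 7.67 CPM in control, at 64.4 CPM in NRG1 1, and at 30.6 and 31.3 CPM in NRG1 2 and NRG1 3. Without NRG1 1 the mitosis list fell by camera with the preset correlation (median -0.65, adjusted p = 2.17e-12). In the 2 against 2 comparison, chosen after seeing the data, 24 of the 26 mitosis genes fell in edgeR (median -0.81; adjusted p = 0.316 for the list with an estimated correlation), as did 8 of the 25 replication genes. With all 6 libraries edgeR called 0 genes of either list over all genes and 0 when adjusted over the list alone, 6 replication genes and 0 mitosis genes had an unadjusted p under 0.05, and DESeq2 called 0. The 2 against 2 comparison, with 1515 calls among 15421 genes, also called members of other lists. Lower were 15 of 24 mesenchymal, 12 of 18 ERK output, 9 of 22 TGF-beta and 8 of 32 interferon genes, and 0 were higher. Higher were 10 of 32 epithelial and 5 of 7 secretory genes, and 0 were lower.

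Among metabolic and stress lists, those of cholesterol synthesis, chaperones and NF-kB cytokines fell. Of 29 genes of cholesterol and fatty acid synthesis, 26 had a fold change below 0 (median -0.59), but 1 gene was lower in all NRG1 libraries. The median relative to the control mean was 0.31, -0.77 and 0.50 in control 1 to 3 and 0.09, -0.95 and -0.88 in NRG1 1 to 3, so control 2 lay near NRG1 2 and NRG1 3, and NRG1 1 lay inside the control range. The cholesterol list fell by camera with the preset correlation (adjusted p = 5.62e-05), with an adjusted p = 0.569 with an estimated correlation. The endoplasmic reticulum chaperone list fell by camera as well (20 tested, median -0.26, adjusted p = 0.00152, and 0.565 with an estimated correlation). HSPA5 and MANF had log2 fold changes of -0.87 (SE 0.26) and -0.95 (SE 0.26). The chaperone median relative to the control mean was -0.18, -0.02 and 0.19 in control 1 to 3. It was -0.02, -0.39 and -0.32 in NRG1 1 to 3, so NRG1 1 lay inside the control range. NF-kB cytokine genes fell by camera (18 tested, median -0.31, adjusted p = 0.0163; adjusted p = 0.565 with an estimated correlation), a call lost without control 3 (adjusted p = 0.315) and in the 2 against 2 comparison (adjusted p = 0.154); RELB was at 51.9 CPM in control 3, 13.1 and 28.1 CPM in the other controls, and 8.79 to 11.8 CPM in NRG1. NRF2 targets were not called as a list by camera (26 tested, median -0.32, adjusted p = 0.104, and 0.749 with an estimated correlation). They fell without control 2 (adjusted p = 0.00778) or NRG1 1 (adjusted p = 0.0319). They also fell in the 2 against 2 comparison (adjusted p = 0.0232), but not there with an estimated correlation (0.601). Among them FTH1, the ferritin heavy chain, was at 797 ± 59.4 CPM in control and 1734 ± 112 CPM in NRG1, with pseudogene copies that could share its reads. AKR1B10 and ALDH3A1, a reductase and an aldehyde dehydrogenase, had log2 fold changes of 2.21 (SE 0.40) and 1.68 (SE 0.39), and the transporter ABCC3 had one of -0.97 (SE 0.17). edgeR called 0 genes of these 4 lists over all genes; adjusted over the list alone it called 0 genes of the first 3 lists and, among NRF2 targets, 3 higher and 2 lower. At an unadjusted p under 0.05 there were 5 cholesterol, 6 chaperone, 4 NF-kB and 8 NRF2 genes, and DESeq2 called 0 cholesterol genes, 1 chaperone gene, 1 NF-kB gene and 4 NRF2 targets.

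The called lists also included 5 others. Genes of cytosolic ribosomal proteins rose as a list by camera with the preset correlation (29 tested, median 0.19, adjusted p = 0.00207; adjusted p = 0.565 with an estimated correlation), and 15 of them were higher in all 3 NRG1 libraries and 0 lower; without control 1 the adjusted p was 0.051. RPS27A was at 778 ± 47.2 CPM in control and 1052 ± 21.3 CPM in NRG1. Replication-dependent histone genes rose (5 tested, median 0.94, adjusted p = 0.00156; adjusted p = 0.326 with an estimated correlation), with H2AC6 at 2.93 ± 1.63 and 7.05 ± 0.650 CPM; most mRNAs of this family lack a polyA tail. Targets of p53 rose (23 tested, median 0.14, adjusted p = 0.0414; adjusted p = 0.749 with an estimated correlation), a call lost without control 1, control 3, NRG1 2 or NRG1 3 (adjusted p = 0.753, 0.0546, 0.275 and 0.207), and TNFRSF10C and TP53I3 had log2 fold changes of 1.67 (SE 0.40) and 0.77 (SE 0.20). The Wnt/beta-catenin list fell (17 tested, median -0.50, adjusted p = 0.00496; adjusted p = 0.326 with an estimated correlation), with WNT5A, a secreted Wnt ligand, at 7.0 ± 1.31 CPM in control and 1.54 ± 1.03 CPM in NRG1. The neuroendocrine cell list fell (6 tested, median -0.84, adjusted p = 0.0194; adjusted p = 0.326 with an estimated correlation), with NCAM1 and ENO2 at log2 fold changes of -1.78 (SE 0.47) and -0.83 (SE 0.26). Neither the Wnt/beta-catenin nor the neuroendocrine call was kept in the 2 against 2 comparison (adjusted p = 0.159 and 0.192), and the neuroendocrine call was also lost without control 3 or NRG1 1 (adjusted p = 0.0541 and 0.0546), in DESeq2 (0.0594), in limma-trend on log2(CPM + 1) (0.064), with quality weights (0.0924) and with GC correction of 2 against 2 libraries (0.201). Of these 5 lists edgeR called 0 genes over all genes; adjusted over the list alone, 1 Wnt gene and 2 neuroendocrine genes were lower. At an unadjusted p under 0.05 there were 2 ribosomal, 2 histone, 2 p53, 4 Wnt and 2 neuroendocrine genes, and DESeq2 called 1 p53 target as higher and 1 Wnt gene as lower. Of the other settings with the preset correlation, 19 were tallied, 5 of them chosen after seeing the data. Limma-trend on log2(CPM + 0.25), which passed 15 lists, was left out of this tally. The call failed in 7 for immediate early and for neuroendocrine genes, and in 5 for NF-kB cytokines and for p53 targets. It failed in 4 for the squamous list, in 3 for ERBB ligands, in 2 for the Wnt list and in 1 each for basal and ribosomal genes. In all, 20 of 32 lists passed by camera with the preset correlation, 0 with an estimated correlation and 0 by fry. At an unadjusted p under 0.05 it was 20, 4 and 9. The other splits of the 6 libraries into 3 and 3 passed 9 to 18 lists with the preset correlation. Other splits of the 2 against 2 comparison passed 13 and 10. A call with the preset correlation is therefore weak evidence by itself. The 12 lists that were not called included those for ciliated cells (median 0.06, adjusted p = 0.78), alveolar epithelial cells (median -0.12, adjusted p = 0.836) and antigen presentation (median 0.11, adjusted p = 0.372; adjusted p = 0.779 with an estimated correlation), which rose without NRG1 1 (adjusted p = 0.035). Of the others, YAP/TAZ targets fell without NRG1 1 (adjusted p = 0.00327) or control 2 (0.0361), and the ATF4 response without control 3 (0.00852). Hypoxia genes fell without control 2 (0.0157) and FOXO targets without control 1 (0.0287) or control 2 (0.0358). With all 6 libraries and an estimated correlation the adjusted p-values of these lists, in this order, were 0.727, 0.779, 0.783 and 0.779. In the 2 against 2 comparison YAP/TAZ targets (adjusted p = 0.00089) and the ATF4 response (0.0133) also fell by camera. With an estimated correlation there the values were 0.404 and 0.567.

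Control 3 and NRG1 1 stood apart from the other libraries of their groups. The first principal component of the log2 CPM, with 44.5% of the variance, placed control 3 at -79.3 and the other controls at -4.16 and 0.682, and the second, with 27.3%, placed NRG1 1 at 65.4 and the other 2 NRG1 libraries at -23.0 and -22.6. In control 3, immediate early genes had a median log2 difference of 2.21 from the other controls and NF-kB cytokine genes one of 1.19. In NRG1 1, mitosis genes had a median log2 difference of 1.53 from the other NRG1 libraries, ERK output genes 1.29, cholesterol genes 1.06 and squamous genes -1.13. NRG1 2 and NRG1 3 were the closest pair: over 13492 genes their counts differed by 2.82 times the variance of sampling, against 20.7 times for control 1 and control 2. They were counted as 2 libraries, although the labels do not say that they came from separate cultures. By the same measure NRG1 1 lay nearer to control 1 and control 2 (36.4 and 39.2 times) than to NRG1 2 and NRG1 3 (48.1 and 42.7 times). NRG1 2 and NRG1 3 also lay nearer to control 2 (29.3 and 26.8 times) than to NRG1 1. Control 3 lay nearer to control 1 and control 2 (72.0 and 62.2 times) than to any NRG1 library (84.8 to 104.8 times). The biological coefficient of variation was 0.285 over all 6 libraries and 0.125 in the 2 against 2 comparison.

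**Figure D3:**
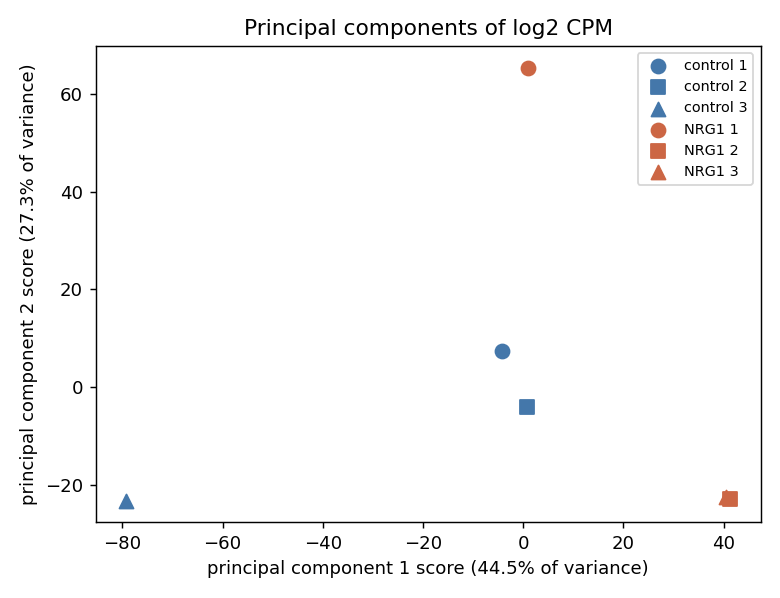
Scores of the 6 libraries on the first and second principal components of log2 CPM, each axis with its share of the variance; blue symbols are control libraries, orange symbols are NRG1 libraries, and the shape gives the replicate number. Control 3 lies at -79.3 on the first component and NRG1 1 at 65.4 on the second, away from the other 4 libraries.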

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

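The tests of a wrong label, of another airway sample and of a response to NRG1 were chosen after their result was seen. Those of GC content and exon number were set before their own result was seen, but after the patterns they address were seen.

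Genes with too few counts to be tested were screened in the secretory, ciliated, alveolar, endothelial, leukocyte, fibroblast and neuroendocrine lists only. Of these genes, 4 had at least 20 expected counts in an NRG1 library and over 3 times the count of every control library. Genes higher in a control library were not screened for. SCGB1A1, a protein of club cells, had 221 expected counts in NRG1 3 and at most 31.0 in a control library. SCGB3A1 had 54 counts in NRG1 3 and at most 7 in a control, MUC5B had 28 and at most 4, and SLC34A2 had 43 and at most 7. The highest of the controls was control 3 for each of these genes.

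Secretory cell transcripts outside the tested genes appeared in control 3 (454 expected counts in sum) and NRG1 3 (626), and summed to 7 to 21 in the other 4 libraries. BPIFB1 had 166 and 173 counts in these 2 libraries and at most 1 in the others. The proportions differed between the 2 libraries. MUC5AC had 135 counts in control 3 and 42.9 in NRG1 3, whereas SCGB1A1 had 31.0 and 221. NRG1 1 and NRG1 2, that is 2 of the 3 NRG1 libraries, held fewer of these transcripts than control 3, which argues against a response to NRG1. Ciliated cell transcripts outside the tested genes summed to 90 in control 3 and 140 in NRG1 3, and to at most 28 in the other libraries. RFX3 and 8 other genes of the ciliated list were among the tested genes and were not used. Their median relative to the control mean was also highest in NRG1 3 (0.62) and control 3 (0.31), with -0.41 to 0.15 elsewhere. The lower of the 2 sums, 90, lay above every other library, as reads or RNA from another airway sample would give. Which sample that would be, and whether reads or RNA were carried over, stays open, as do rare differentiated cells in these cultures; ALB (23.02 counts in control 3, at most 1 in any other) and HBB (9 in NRG1 3, 0 in the others) are not typical of airway cells, but these counts are too few to decide.

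Immediate early genes lay 2.21 (median log2 difference, 22 genes) above the other controls in control 3. The difference was 2.28 (bootstrap SD 0.489) after a correction for GC content, so that trend does not account for it. Single-exon genes had a median log2 difference of -0.45 in that library, and a correction for this lower yield could only enlarge the difference, which it did (2.55, bootstrap SD 0.562), so it decides nothing. NRG1 in control 3 was at 1.26 times the mean of the other controls, which argues against an NRG1 library under a wrong label. The design gives control 3 no treatment of its own, and no biological explanation was tested.

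Mitosis genes lay 1.53 (median log2 difference, 26 genes) above the other NRG1 libraries in NRG1 1. The difference was 1.56 (bootstrap SD 0.0602) after a correction for GC content, although this library differed by 0.27 in the genes of lowest GC content and by -0.22 in those of highest (10% of genes each). NRG1 in this library was at 1.74 times the mean of the other NRG1 libraries, which argues against a control library under a wrong label. No biological explanation was tested.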

How the results depend on the processing

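The comparisons of 2 against 2 libraries, quality weights, older dispersion method and GC correction were chosen after seeing the data. NRG1 passed in each alternative, with log2 fold changes from 8.49 to 8.95. For the 4 gene counts (all, higher, lower, at least 2-fold), DESeq2 gave 209, 92, 117 and 168, no low-count filter 21, 10, 11 and 21, limma-voom without rounding 2, 2, 0 and 2, and GC correction 4, 3, 1 and 4. The comparison of 2 against 2 libraries gave 1515, 777, 738 and 619, and GC correction with 2 against 2 libraries 1563, 786, 777 and 581; quality weights gave 1602, of which 701 were higher, the rest lower and 640 changed at least 2-fold. Leaving out 1 library gave 1 to 37, 1 to 27, 0 to 10 and 1 to 37; the upper ends came without NRG1 1 and all other removals left 1. The older dispersion method, other scalings, the 1 CPM filter and limma-trend each gave 1. The second voom gene has the identifier ENSG00000256514 and no symbol. The GC-corrected calls beyond NRG1 were PPP1R16B, MUC1 and COL5A1. Of 59 genes beyond NRG1 that were followed through the settings, 11 passed without the low-count filter. Quality weights were 0.185 for control 3 and 0.245 for NRG1 1, and 1224 of their calls were shared in direction with the 2 against 2 calls. The cause of the other differences was not tested.

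With the replicate block edgeR called 2 genes, 1 higher (NRG1), 1 lower (FN1), 2 changed at least 2-fold, and 21 lists. Same-numbered libraries correlated in their deviations by 0.02, 0.12 and -0.08, which shows no pairing by number. These values cannot exclude one, because control 3 and NRG1 1, which stood apart, carry different numbers. Control 3 and NRG1 3 also held the most airway secretory transcripts outside the tested genes.

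By camera 15 to 24 lists passed in the settings with a preset correlation (17 to 24 when 1 library was left out), 0 with an estimated correlation, 0 by fry, and 0 of 2 against 2 libraries with an estimated correlation. Of the 20 called lists, immediate early genes turned, without control 3 (medians without 1 library -1.13 to 0.39). The other lists that turned were not called with all 6 libraries. Mitosis turned in DESeq2 (median 0.037). With 1 library left out the medians ran from -0.65 to 0.28 for mitosis, -0.18 to -0.023 for the ATF4 response, -0.21 to 0.0036 for hypoxia, -0.43 to 0.082 for FOXO targets, -0.12 to 0.31 for ciliated cells, -0.20 to 0.20 for alveolar cells, -0.15 to 0.050 for ERBB receptors, -0.18 to -0.013 for proteases and -0.24 to 0.034 for Notch genes. In 2 against 2 libraries (either correlation), with GC correction there and with quality weights, the medians were 0.061, 0.047 and 0.024 for ERBB receptors, -0.14, -0.15 and -0.17 for proteases, and 0.10, 0.085 and 0.21 for Notch genes; for FOXO targets the first 2 were -0.029 and -0.020. Turning refers to the direction of the test, which can differ in sign from the median.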

Other observations

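The genes of this paragraph lie outside the lists or were chosen after their values were seen. ALPP, a placental alkaline phosphatase with close copies in the genome, was at 0.512 ± 0.130 CPM in control and 6.39 ± 1.85 CPM in NRG1 (SD, n = 3 each). GALNT5, an enzyme that starts O-glycans, was at 3.23 ± 1.81 and 18.9 ± 4.64 CPM, WFDC2 was at 3.13 ± 1.24 and 20.7 ± 12.4 CPM, and CAMK2B, a calcium-dependent kinase, was at 2.26 ± 1.00 and 16.0 ± 7.12 CPM. IL11, a cytokine, was at 18.7 ± 13.7 CPM in control and 2.37 ± 0.737 CPM in NRG1, and the glucose transporter SLC2A3 was at 30.8 ± 30.7 and 4.36 ± 2.07 CPM. These 6 genes passed DESeq2, the first 4 as higher and the last 2 as lower, with adjusted p-values of 8.81e-08, 3.91e-06, 0.000409, 5.79e-06, 3.49e-05 and 0.00221. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment none passed, with adjusted p-values from 0.0902 for ALPP to 0.318 for SLC2A3.

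Levels of single genes, chosen after they were seen, show how far the libraries within a group lay apart. FOS was at 27.6, 42.7 and 493 CPM in control 1 to 3 and at 246, 145 and 101 CPM in NRG1 1 to 3, above control 1 and control 2 and below control 3. EGR1 was at 184, 271 and 3794 CPM in control 1 to 3 and at 1020, 173 and 144 CPM in NRG1 1 to 3. DUSP6, an ERK phosphatase, was at 46.3, 38.7 and 289 CPM in control 1 to 3, 72.9 CPM in NRG1 1, and 12 and 11.9 CPM in NRG1 2 and NRG1 3. TOP2A was at 1174 CPM in NRG1 1 and 445 and 467 CPM in NRG1 2 and NRG1 3, with 446 to 738 CPM in the controls. The protease KLK7 was at 4.20 CPM in NRG1 1 and 88.6 and 98.5 CPM in NRG1 2 and NRG1 3, with 14.5 to 19.8 CPM in the controls.

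The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real groups gave 1 gene past the threshold, and the highest other split gave 4, so 2 of the splits gave as many. The same 2 splits gave as many genes on 1 side, where the real groups gave 1 higher gene and the highest other split 2, and as many genes changed at least 2-fold, where the real value was 1 and the highest other 4. For lower genes the real value was 0 and the highest other 2, and all 10 splits gave as many. The real groups gave 20 gene lists and the highest other split 18, so 1 of the splits, the real one, gave as many. The 20 lists include that of ERBB ligands, which holds the overexpressed gene itself and had a camera p of 0.44 without NRG1. The split with 4 genes set control 1, control 3 and NRG1 1 against the other 3 libraries and had 2042 genes at an unadjusted p under 0.05, against 1819 for the real groups. Its genes were CYP51A1 and FDFT1 of sterol synthesis, INPP5D and TRIM22.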
